A study of Mus musculus with 3 samples.

How the data were processed

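Gene expression was measured in the neural retina of wildtype mice at postnatal day 21 on Affymetrix U74Av2 arrays, which carry short-oligonucleotide probe sets and are read in a single colour. Per the labels, the animals had a mixed 129/SvEv and C57BL/6 background and were unaffected siblings of Rp1-null animals studied in parallel, each RNA came from a pool of retinas of 3 to 4 mice, and the tissue was taken between 1 and 2 pm. The labels place 3 arrays in 1 group. They were numbered in accession order as pools 1, 2 and 3, a number that only names a pool. The labels name pools but say nothing more of how independent they were, so the spread between arrays may hold technical as well as animal variation. The Rp1-null arrays were not analysed here.

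The deposited values were linear signal intensities, 1 per probe set and array, with none at or below 0. After the lowest and highest 2% of probe sets were left out, the mean intensity was 500 on every array (500.3, 500.3 and 500.3), so the authors' deposited table had been scaled array by array. The software, its version and the probe mask are not given in the sources used here, and no detection call was used. Each array held 12488 probe sets, of which 66 were controls. Of the other 12422, 10833 had 1 gene symbol in the platform annotation, 396 had several and 1193 had none; only those with 1 symbol were given a gene name. Symbols were checked through Entrez identifiers, which matched for 10817 probe sets and changed 0 symbols. The named probe sets stood for 8251 genes, of which 2073 had more than 1 probe set; the probe set with the highest mean signal then stood for the gene.

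A floor took the place of detection calls. On each array it was the 90th percentile of 62 probe sets for 52 genes of other tissues, such as liver, pancreas and testis, and came to 306.5, 295.8 and 269.9 in pools 1, 2 and 3. The arrays were then multiplied by 0.991, 1.01 and 1.00 so that the median log2 signal of probe sets above the floor was equal, values under the common floor of 290.7 were set to it, and log2 was taken. The common floor decided every count, so a signal between it and an array's own percentile counted as above. By this rule 7 of the 62 background probe sets still counted as above the floor. Signals are printed as deposited; folds and log2 values are on the scaled, floored scale. A fold whose lower pool lay at the floor is given as "at least", and values under the floor have no order.

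With 1 group there was no contrast between conditions and no p-value for one. The spread was the SD of log2 signal over the 3 arrays. A gene's deviation in a pool was its log2 signal there minus its mean in the other 2 pools. The number of arrays limits the precision of every value. For 29 gene lists of cell types, neighbouring tissues and cell states, the members above the floor were counted. Where a list had at least 4 such members, its median deviation was ranked among 10000 random lists of the same size matched on mean signal in 20 bins, and was singled out below the 1st or above the 99th percentile. This describes these arrays and is not a test of significance. The lists, the floor, the ranking rule and the rule for naming genes were fixed before the data were examined. So were the alternatives, apart from those named below as chosen later. The rule named Rp1, the first 2 genes of each list on the array, the 10 genes with the highest SD, the 3 members furthest in a singled-out list's direction, and every measured sex-linked gene. Rp1 itself was not analysed here. Other genes named in the text were chosen after their values were seen.

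The list ranking was tested on simulated data for 4375 genes. It recovered 38 of 40 lists shifted by 0.40 on the log2 scale in 1 array and 40 of 40 shifted by 0.80. Of 1140 values of lists with no shift, 36 (3.16%) were singled out, against the nominal 2%. Each simulated gene varied independently of the others, with the same spread on all arrays. Every member of a shifted list was given the same shift, and the simulated values were not set to the floor. Members of a real list may vary together, go both ways or lie at the floor, so these rates may not hold for real lists. Alternatives were other floors, no floor, deposited values without scaling, and quantile and cyclic loess normalisation. Others were other rules for genes with several probe sets, only unsuffixed probe sets, and leaving out each array in turn. Unsuffixed names lack the letters f, r, i, s or g before their ending. Some of these suffixes mark possible matches to several genes. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.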

Results

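Neural retina from 3 pools of wildtype mice at postnatal day 21 was profiled, 1 array per pool, in 1 group. The labels present these animals as siblings of mice lacking Rp1, a gene of photoreceptor axonemes, so the arrays describe the normal retina beside which the mutant was studied. The median signal of all 12488 probe sets, controls included, was 235.2 in pool 1, 226.0 in pool 2 and 229.9 in pool 3. In their mean over the pools, 5542 probe sets lay above the floor, and 5538, 5490 and 5565 did so on the single arrays.

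Most measured genes of 7 of the 8 retinal lists lay above the floor in their mean, the exception being astrocytes. For horizontal cells and astrocytes this depended on the floor rule, as given below. All 17 measured rod genes lay above the floor on every array, among them Gnat1, the alpha subunit of rod transducin (50666 ± 9411, SD, n = 3, as for all values given with ±), Pde6b, a subunit of the rod phosphodiesterase (16945 ± 422), and Sag, the rod arrestin (39693 ± 3840). Of 8 cone genes, 5 lay above the floor, including the short-wave opsin Opn1sw (4200 ± 708) and the middle-wave opsin Opn1mw (1900 ± 391), while Cnga3, Thrb and Rxrg did not. The bipolar cell list had 6 of 7 genes above the floor, with the ON-bipolar channel Trpm1 at 371.7 ± 59.6 and Pcp2 at 2489 ± 689. Müller glia had 10 of 11, with glutamine synthetase, Glul, at 2564 ± 558 and the retinaldehyde-binding protein Rlbp1 at 4477 ± 505. Retinal ganglion cells had 9 of 10, with Thy1 at 2593 ± 291 and the neurofilament gene Nefl at 1492 ± 130.

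Amacrine cells had 10 of 15 genes above the floor. Gad1, which makes GABA, was at 5607 ± 439, and its paralogue Gad2 was under the floor on all 3 arrays. Horizontal cells had 4 of 7 (57.1%), near the 53.0% of all named genes, and 2 of the 7 passed on every array. The calcium-binding protein Calb1 was at 958.9 ± 68.8, and the transcription factor Lhx1 was under the floor in all pools. The astrocyte list had 2 of 6, Pdgfra and Aldoc. Under floors from the array median, the 75th background percentile and the bacterial and yeast controls it had 4, 5 and 6. Gfap had a mean under the floor (265.4 ± 34.1), and its 303.1 in pool 1 passed the common floor but not that array's own background percentile. Pax2 was under the floor in all pools. Over the 8 retinal lists 63 of 81 entries (77.8%) lay above the floor, against 4375 of all 8251 named genes (53.0%). A few genes, such as Nefm, stand in more than 1 list.

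**Figure D1:**
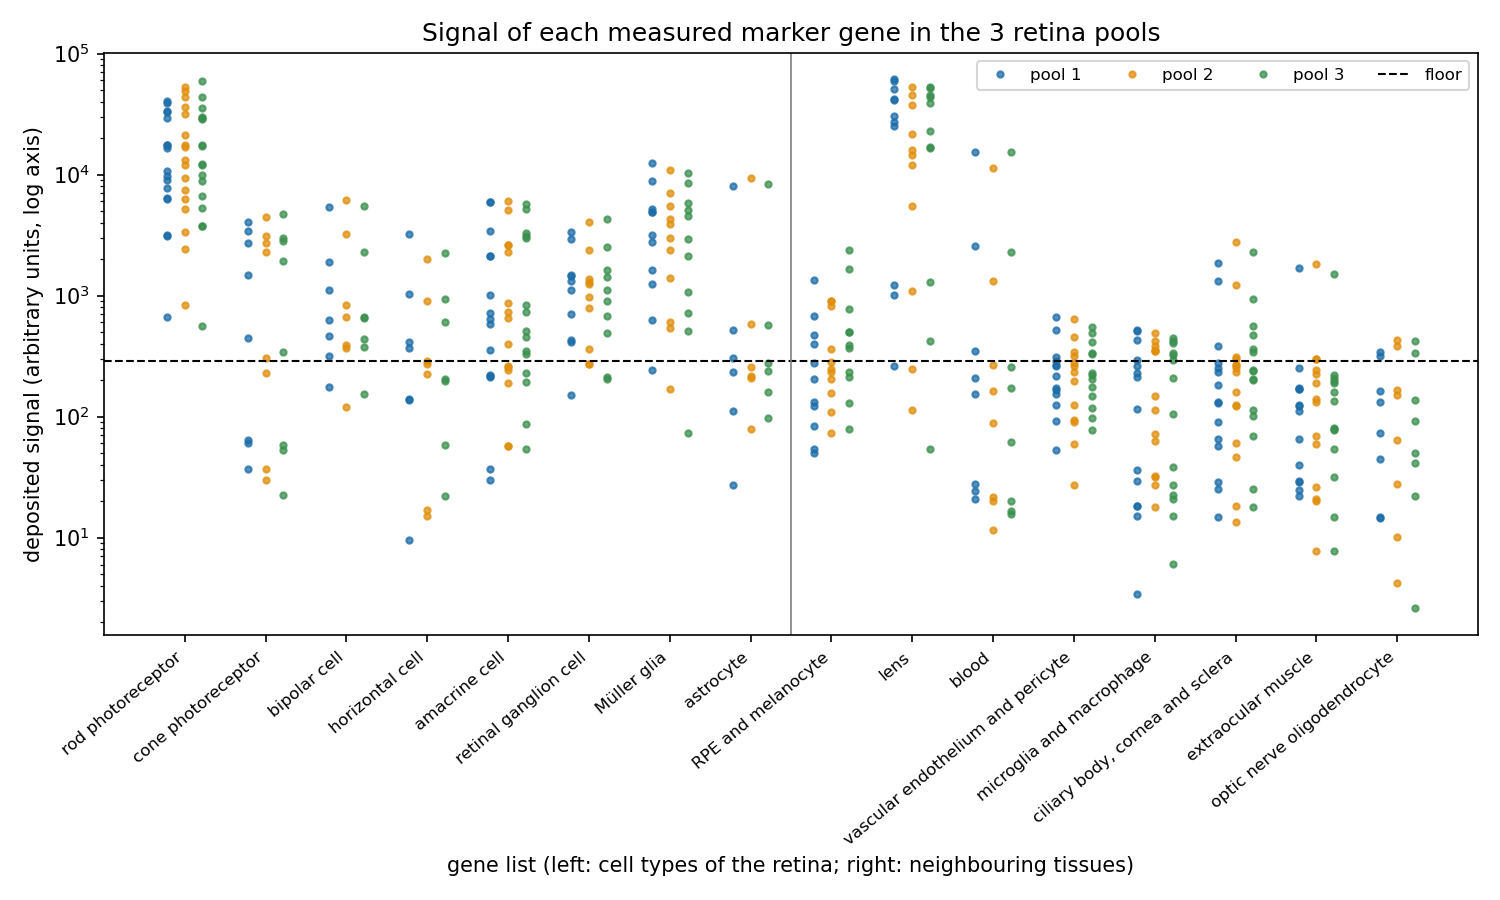
Deposited signal (arbitrary units, log axis) of each measured marker gene, with 1 point per gene and pool, for the 8 lists of retinal cell types on the left and the 8 lists of neighbouring tissues on the right; the dashed line is the common floor of 290.7. All 17 rod genes and 10 of 11 lens genes had a mean above the floor, while 13 of 14 extraocular muscle genes had a mean under it.

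Genes of tissues in or beside the retina differed in how many lay above the floor. Blood, vessels and microglia also lie within the retina. Of the 94 entries in the 8 lists of neighbouring tissues, 37 (39.4%) lay above the floor. Lens had 10 of 11, among them the crystallins Cryaa (55398 ± 4922) and Cryba1 (44143 ± 2101), and the retinal pigment epithelium and melanocyte list had 6 of 11. Blood had 2 of 8, the globins Hbb-b2 (2061 ± 649) and Hba-a1 (14024 ± 2260). Microglia and macrophages had 6 of 14, with Csf1r at 322.5 ± 29.3 and the fractalkine receptor Cx3cr1 at 352.0 ± 130, both under the floor in pool 1. Vascular endothelium and pericytes had 5 of 13, with Pecam1 at 313.3 ± 21.3 and Cdh5 under the floor. The ciliary body, cornea and sclera list had 5 of 15, without the corneal keratin Krt12 and with Aldh3a1 above the floor in pool 3 alone (340.5). Muscle had 1 of 14, the calcium buffer Pvalb, which retinal neurons also express, and neither Acta1 nor Myh2. Oligodendrocytes had 2 of 8, with the myelin gene Mbp at 396.9 ± 50.2 and Mobp under the floor. These shares depended on the floor. Under floors from the array median, the 75th background percentile and the bacterial and yeast controls, muscle had 2, 7 and 8. Vascular endothelium and pericytes had 6, 9 and 12, and the ciliary body, cornea and sclera list had 6, 10 and 12. Each of the 8 lists had more members above the control floor, as did all probe sets (8882 against 5542).

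Metabolic and synaptic genes were broadly expressed. All 15 glycolysis genes lay above the floor, including the hexokinases Hk1 (4130 ± 99.8) and Hk2 (3656 ± 581), as did 16 of 20 oxidative phosphorylation genes, with Ndufa2 at 1507 ± 192 and Ndufa1 under the floor. The synaptic vesicle list had 9 of 10, with Syt1 at 4941 ± 340 and Snap25 at 12917 ± 913. The cytosolic ribosome list had 11 of 15, with Rpl7 at 9186 ± 584 and Rpl8 at 7099 ± 804. Rpl32, Rps14, Rps15 and Rps20 were under the floor. Here and in the other lists, a probe set under the floor does not show that its gene was not expressed. The sterol synthesis list had 9 of 14, with Hmgcs1 at 1455 ± 235 and Sqle at 1178 ± 270. Heat shock genes had 12 of 13 above the floor, with Hspa1a at 816.9 ± 350 and Hspa1b at 637.9 ± 238. Of the clock genes 11 of 14 lay above it, with Per1 at 562.3 ± 67.1 and Per2 under it in every pool.

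Genes of division, interferon signalling and injury had a minority of their members above the floor. The cell cycle list had 4 of 16 (Ccnb2, Ccna2, Pcna and Plk1), and the proliferation genes Mki67 and Top2a were under it on all arrays. The interferon list had 1 of 14, Irf9, and neither Ifit1 nor Ifit2 passed. The retinal stress and injury list had 6 of 14, without the photoreceptor injury signal Edn2. The immediate early list had 9 of 15, with Fos at 697.4 ± 154 and Fosb at 332.6 ± 42.1. The strain-variable list had 8 of 12, with the class I histocompatibility genes H2-D1 (980.1 ± 154) and H2-K1 (724.7 ± 94.9), both on probe sets that may match several genes. With the array median as floor, which is lower, the cell cycle, interferon, and stress and injury lists had 9, 1 and 8 members above it, and with a floor from the bacterial and yeast controls 13, 5 and 11.

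The comparison open to this design is between the 3 pools of one genotype. For most genes they differed little, with a median SD of 0.22 on the log2 scale (1.17-fold) and a 95th percentile of 0.54 over the 5542 probe sets above the floor. The median SD was 0.23 in the dimmest 1386 by mean signal and 0.20 in the brightest 1386. In 298 probe sets (5.38%) some pair of pools differed by more than 2-fold. Pools 1 and 2 differed so at 177 probe sets, 78 higher in pool 1 and 99 in pool 2. Pools 1 and 3 did at 178, 79 higher in pool 1 and 99 in pool 3. Pools 2 and 3 did at 38, 15 higher in pool 2 and 23 in pool 3. The Pearson correlation of log2 signal across these probe sets, which are not independent replicates, was 0.933 and 0.931 for the pairs with pool 1 and 0.967 for pools 2 and 3. Without pool 1, 43 probe sets were over 2-fold apart; without pool 2, 182; without pool 3, 170.

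The genes that varied most between pools were led by Ankrd33b, at 103.5, 559.8 and 1708 in pools 1, 2 and 3, which is at least 5.89-fold from highest to lowest. Pla2g1b, a secreted phospholipase, was lower in pool 1 (301.6) than in pool 2 (1292) and pool 3 (1279). Its pool 1 signal was under that array's own background percentile of 306.5, so no fold is given, and its only probe set carries a suffix. Skp1, a subunit of ubiquitin ligases, was at 1268 in pool 1 against 4632 and 4427 in the others. Krt81, a hair keratin, was at least 3.38-fold lower in pool 1 than in pool 3 on the brightest of its 4 probe sets. Its other probe sets were under the floor in every pool. Ptgds, the prostaglandin D synthase, was 4.03-fold lower in pool 1 (1321) than in pool 3 (5265) on its brightest probe set. All its probe sets carry a suffix, and those other than the brightest may match several genes. These others differed from each other, 1 reading 1527, 2434 and 3606 in pools 1, 2 and 3 and 1 reading 2481, 2765 and 2536. Arih1 spanned 3.90-fold between pool 2 (1683) and pool 3 (434.1), and its second probe set read 593.6, 596.1 and 542.0. Xist, Crygb, Bfsp1 and Dct complete the 10 and are described with their lists.

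**Figure D2:**
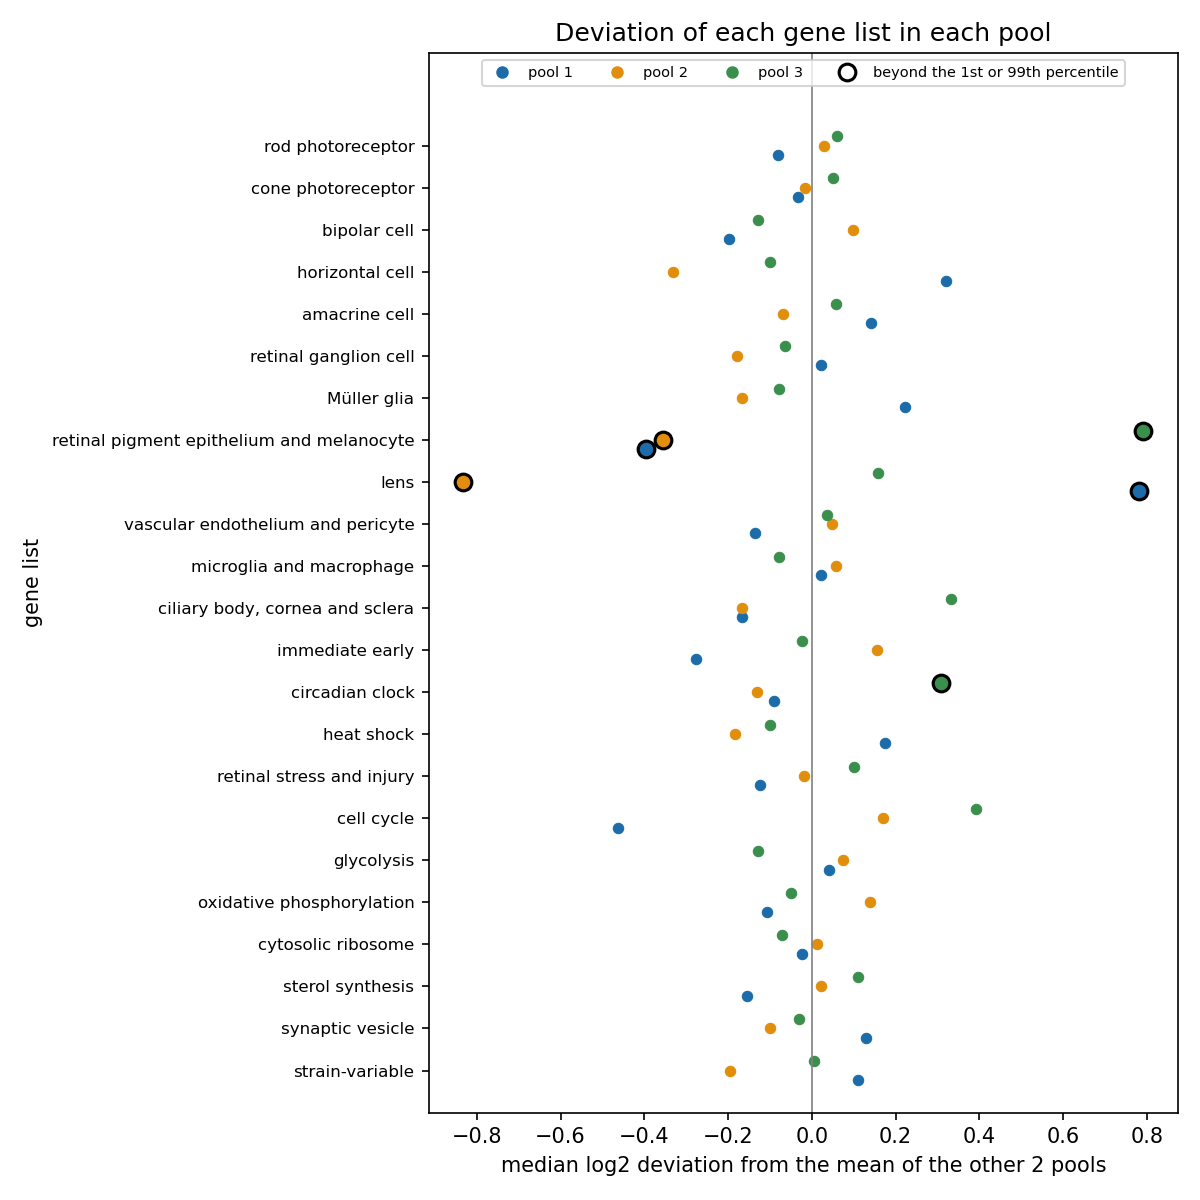
Median log2 deviation of each of 23 gene lists in each pool from the mean of the other 2 pools (horizontal axis), with 1 point per list and pool; outlined points lie below the 1st or above the 99th percentile of matched random lists. The lens list in pools 1 and 2 (0.78 and -0.83) and the pigment epithelium list in pool 3 (0.79) lie furthest from 0.

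Lens genes differed together between pools, but not all of them did. The gamma-crystallins, which fill lens fibre cells, were lowest in pool 2. Crygb was at 25092, 5502 and 16867 in pools 1, 2 and 3, a 4.49-fold range. Crygc was at 30754, 12084 and 22991, Crygd at 51201, 16091 and 43726, and Cryge at 58912, 21644 and 52272. Crybb2, a beta-crystallin, was at 26976, 14429 and 16732 (1.84-fold). The fibre cell filament gene Bfsp1 was at 1235, 248.1 and 423.4, at least 4.21-fold higher in pool 1 than in pool 2. Cryaa, Cryba1 and Crygs differed by at most 1.15-fold, and Mip, the lens water channel, by 1.29-fold. The median deviation of the 10 lens genes was 0.78 in pool 1 (percentile 100 of the random lists) and -0.83 in pool 2 (percentile 0), with 9 of 10 genes lower in pool 2, and 0.16 in pool 3 (percentile 94.6). With only unsuffixed probe sets, 7 genes remained, and the values in pools 1 and 2 were 0.20 and -0.09, inside the bounds. Without pool 2, the pool 1 value was 0.21 (percentile 97.1), inside the bounds. Without pool 1, pool 2 stood at -0.42 (percentile 0) and pool 3 at 0.42 (percentile 100), past the bounds. With 2 pools left these are 1 difference given with opposite signs.

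Melanin synthesis genes were highest in pool 3. Dct, a melanin-synthesis enzyme, was at 679.6, 897.7 and 2389 in pools 1, 2 and 3 (3.56-fold from highest to lowest), and Pmel, a scaffold of the melanosome, was at 470.1, 894.0 and 1668 (3.59-fold). Tyrp1 and the retinol and thyroxine carrier Ttr were above the floor in pool 3 alone, at 501.0 and 503.5, each at least 1.73-fold higher there. Tyr was under the floor in all pools. The epithelial genes of the list went the other way, Krt18 at 1358, 817.1 and 778.8 and Cdh3 at 395.7, 365.4 and 233.5. The list's median deviation over 6 genes was 0.79 in pool 3 (percentile 100), -0.40 in pool 1 (percentile 0.40) and -0.36 in pool 2 (percentile 0.62). The medians in pools 1 and 3 lay between the deviations of Ttr (-0.398 and 0.796) and Tyrp1 (-0.394 and 0.789). Both genes were under the floor in pools 1 and 2. With genes required above the floor on every array, 3 remained, under the 4 needed for ranking. Without pool 3, pool 2 lay above pool 1 by 0.16 and neither was past the bounds. Without pool 2 the pool 1 value was -0.81, and without pool 1 the pool 2 value was -0.82.

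Clock genes were higher in pool 3, with 10 of 11 members above their mean in the other pools and a median deviation of 0.31 (percentile 99.8). Cry2, a repressor of the clock, was at 464.7, 686.2 and 920.8 in pools 1, 2 and 3 (2.00-fold), Per3 at 289.6, 368.5 and 567.2 (at least 1.96-fold), and the nuclear receptor Nr1d1 at 1116, 805.7 and 1491 (1.84-fold from pool 2 to pool 3). Tef was lower in pool 3 (1313) than in pool 1 (2165). The median was 0.20 under a lower floor (the 75th percentile of the background probe sets), where it no longer passed the bound, and 0.29 without pool 2 (percentile 95.7), where it did not pass either.

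The other 20 lists with at least 4 genes above the floor stayed inside the bounds in all 3 pools, though 5 of them passed a bound in some pool under an alternative setting. Rods had medians of -0.08, 0.03 and 0.06, at percentiles 46.6, 24.9 and 73.7 of equally bright random lists, whose median in pool 1 was -0.07. Single rod genes spanned from 1.05-fold (Abca4) to 3.24-fold for Prph2, a disc rim protein, at 8994, 17509 and 28789, with Gnat1 at 1.47-fold and Pde6b at 1.06-fold. Müller glia had 0.22, -0.17 and -0.08, with percentiles of 98.2, 1.20 and 15.3. Of the 69 values for 23 lists, 6 passed the bounds in 3 lists. The nominal 2% would give 1.38, and the rate in simulated lists of independently varying genes with no shift would give 2.18. The 3 values of a list are not independent of each other. The blood, astrocyte, muscle, oligodendrocyte, interferon and sex-linked lists were too small for this ranking.

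Sex-linked genes differed between the pools. Xist, the RNA that silences 1 X chromosome in female cells, was at 1242, 3609 and 6114 in pools 1, 2 and 3 (4.98-fold). The Y-linked Eif2s3y was above the floor in pool 1 (392.2) and pool 2 (305.1) and read 10.8 in pool 3, at least 1.34-fold lower than in pool 1, on a probe set that may match several genes. The Y-linked Uty (206.3, 70.9 and 71.0) and Kdm5d (57.8, 19.3 and 24.2) were under the floor in every pool. The labels do not give the sex of the mice.

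**Figure D3:**
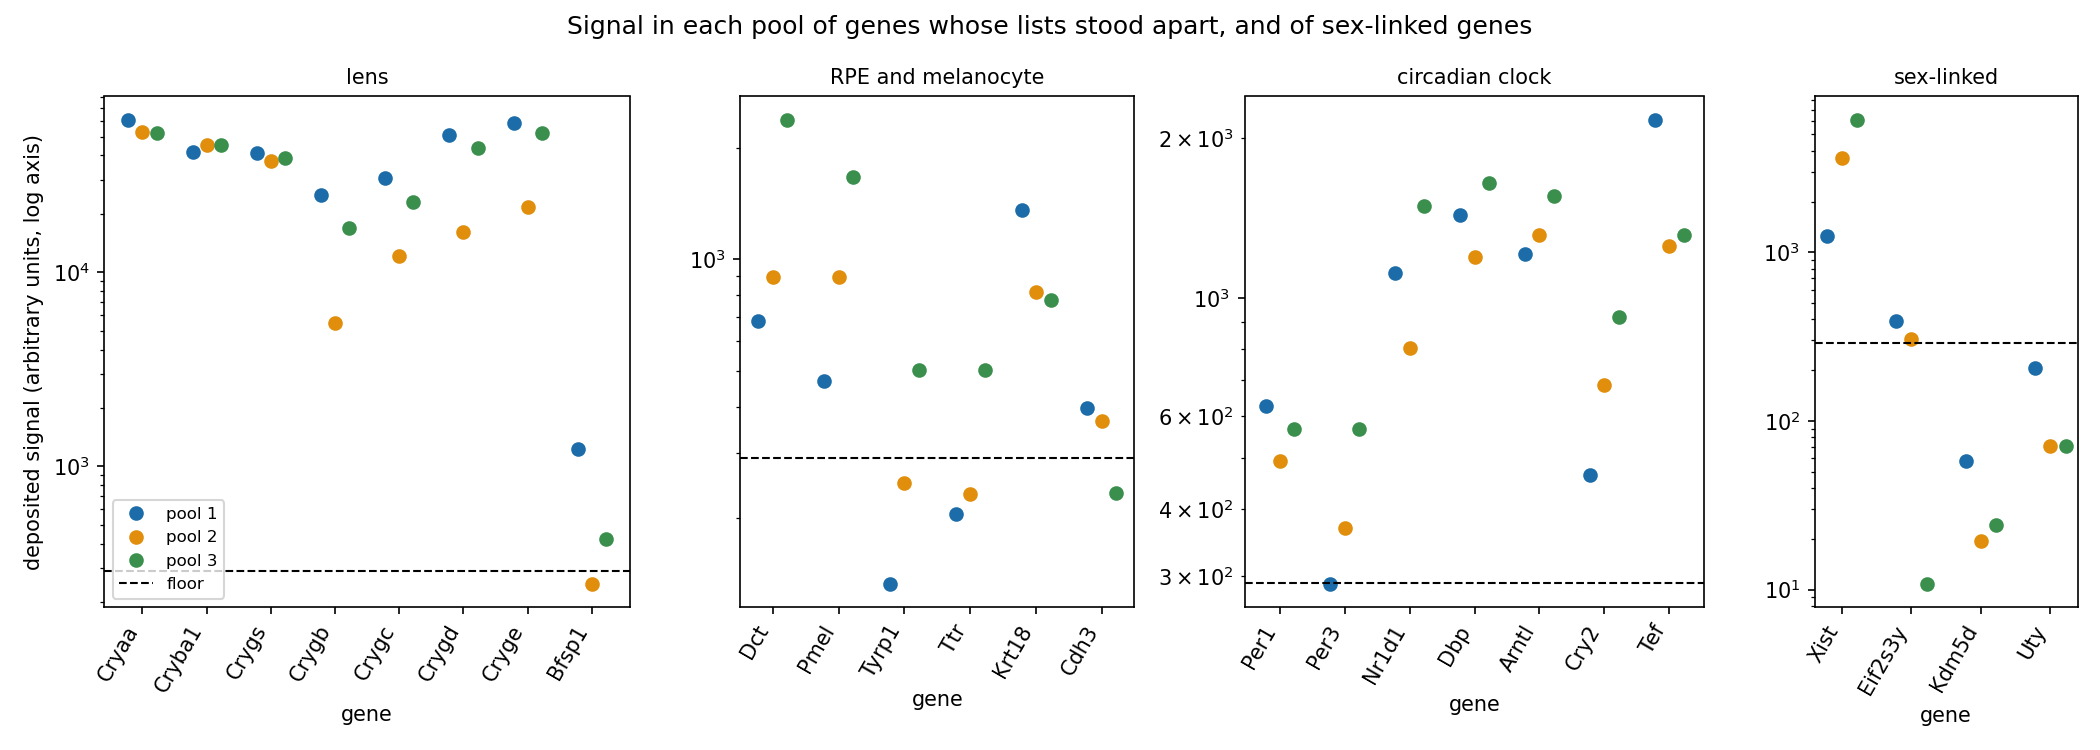
Deposited signal (arbitrary units, log axis, a separate scale in each panel) in each pool of selected lens, pigment epithelium and melanocyte, clock and sex-linked genes; each point is 1 pool and the dashed line is the floor of 290.7. Crygb ranges from 5502 in pool 2 to 25092 in pool 1, Dct from 679.6 in pool 1 to 2389 in pool 3, and Xist from 1242 in pool 1 to 6114 in pool 3.

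Control probe sets gave a view of the RNA and the labelling. The ratio of 3' to 5' signal was 0.916, 0.856 and 0.755 for Gapdh in pools 1, 2 and 3 (0.842 ± 0.0815) and 1.77, 1.56 and 1.47 for beta-actin (1.60 ± 0.153). The 5' probe sets of the transferrin receptor and pyruvate carboxylase were under the floor, so their ratios carry little information.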

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

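The tests chosen after the results were seen were that of control ratios, the split of crystallins by class, the values of Crygb and Crygc on unsuffixed probe sets, the omission from the second pigment list of Pmel, which the first list already holds, and the rules on spread and on members going both ways for the second lists. The percentiles of the second lists as written, of the unsuffixed lens list and under other scalings, and the cyclic loess ratio, were set out beforehand.

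Signal was present in probe sets outside the gene comparisons. All 9 bacterial and phage hybridisation controls (BioB, BioC, BioD and Cre) were above the floor on every array, and all 9 were lower in pool 1. They averaged 1.5-fold higher in pool 2 than in pool 1 (from 1.30 to 1.89) and 2.02-fold higher in pool 3 than in pool 1 (from 1.30 to 2.67). The deposited signals had been scaled array by array, so these folds are relative to the other probe sets of each array. Of 1589 probe sets without a single gene name, 444 were above the floor on every array. The one that varied most between pools read 316.6, 553.8 and 1511 in pools 1, 2 and 3.

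The gamma-crystallins Crygb, Crygc, Crygd and Cryge had a median deviation of -1.44 in pool 2, while Cryaa, Cryba1, Crybb2 and Crygs had -0.09, though Crybb2 itself was at -0.54. Cryaa had the highest signal of array 1 (61080), and whether such bright signals were compressed was not tested. Cryge, at 58912 in pool 1, still spanned 2.68-fold. Lens tissue carried over in differing amounts may account for the lower gamma-crystallins. A second list of 6 lens-related genes, several of them also expressed in retina, however lay at percentile 14.3 in pool 2 (median -0.13). That was past the 10 set as the bound against carry-over, though by less than the SD of random lists (0.143) and with members on both sides (Capn3 and Fabp5 lower, Gja1 higher), so it does not decide. Probe sets shared between gamma-crystallins may also play a part, since without suffixed probe sets the lens list lay at percentile 10.9, inside the bounds, which met the prediction for shared probe sets. That list had however lost its suffixed gamma-crystallins and Bfsp1, and Crygb and Crygc, on probe sets without a suffix, still deviated by -1.89 and -1.12, so this stays open, and no biological explanation was tested.

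The melanin genes Dct and Pmel were highest in pool 3, and scaling between arrays is argued against, since the list stayed at percentile 100 with deposited values, quantile and cyclic loess normalisation. Pigment epithelium or choroid carried over with the retina may explain it, but a second list reached only percentile 59.3 in pool 3 with the 4 genes above the floor that the first list lacks (Timp3, Col18a1, Ezr and Gas1). As first written, with Pmel, it had 5 genes and reached percentile 85.9, under the 90 set as the bound against carry-over. Of the 4 genes 2 were higher and 2 lower in pool 3, so the test decides nothing, and Krt18 and Cdh3 of the first list were lower there. Among that list's genes with a mean under the floor, Rgr and Rdh5 passed it in pool 3 alone (388.0 and 372.2). Tyr, Mitf and Slc16a8 passed it in no pool. No biological explanation was tested.

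Array 1 stood apart, with 177 and 178 probe sets over 2-fold from pools 2 and 3 against 38 between those. A signal-dependent scaling difference is argued against as the whole cause: after cyclic loess the counts were 176, 182 and 41, a ratio of 4.29 for the lower count with array 1, where at most 1.5 was predicted. RNA quality or labelling of array 1 may contribute, since in 2 of 2 control genes above the floor, Gapdh and beta-actin, the 3' to 5' ratio was highest there. For Gapdh, however, pool 2 (0.856) lay nearer to pool 1 (0.916) than to pool 3 (0.755). For beta-actin pool 2 (1.56) lay nearer to pool 3 (1.47) than to pool 1 (1.77). With 2 genes and 3 arrays the highest ratios on array 1 cannot be told apart from chance. The hybridisation controls, lower on array 1 relative to its scaled signal, do not separate labelling from hybridisation. No biological explanation was tested.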

How the results depend on the processing

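The count of probe sets over 2-fold apart on unsuffixed probe sets and the control ratios without each pool were alternatives chosen after the data were seen. No paired analysis was possible because the labels give 1 group. Of 1216 alternative values, 1122 kept their side of the bounds or stayed near their value, 13 left the bounds, 21 newly passed them, 1 reversed and 59 moved. Direction was compared only for the 6 list values past the bounds, so a change of sign inside the bounds was not counted. The count above the floor (5542) was 8882 with a floor from the bacterial and yeast controls and 12422 with no filter. The 298 probe sets over 2-fold apart became 1429 with that control floor, 931 with the 75th percentile floor, 4251 with no filter, and 43 to 182 with 1 pool left out; lower floors admit dim probe sets, and fewer pools give fewer pairs. The median SD ranged from 0.14 without pool 1 to 0.36 with no filter.

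The pigment epithelium list in pool 3 stayed above the 99th percentile in all 11 alternatives that ranked it, from 0.79 to 1.28 (control floor). Its pool 2 value (-0.36) was -0.32 with the array median as floor, -0.15 with the control floor, -0.030 with the 75th percentile floor, -0.0094 with no filter and -0.28 with the mean of all probe sets, all inside the bounds; with 1 pool left out it ran from -0.82 to 0.16, reversed without pool 3. Its pool 1 value ran from -0.81 to -0.16 with a pool left out, inside the bounds without pool 3, and with lower floors or no filter it ran from -0.57 (array median) to -1.03 (75th percentile), with -0.91 for the control floor, and was -0.76 with the mean of all probe sets. The clock list in pool 3 (0.31) was 0.21, 0.20 and 0.20 with the control floor, the 75th percentile floor and no filter, all inside the bounds, and 0.29 to 0.31 with a pool left out, inside the bounds without pool 2. With unsuffixed probe sets the lens list was 0.20 in pool 1 and -0.088 in pool 2; with a pool left out its pool 1 value ran from 0.21 to 1.11 (lowest, and inside the bounds, without pool 2), and its pool 2 value (-0.83) from -1.11 without pool 3 to -0.42 without pool 1, past the bounds in both. That pool 2 value was -0.52 with the control floor or no filter. The lens list in pool 3 (0.16) passed the upper bound without pool 1 (0.42) and when genes had to pass the floor on each array (0.26), and was -0.21 without pool 2. The clock list in pool 2 (-0.13) passed the lower bound without pool 1 (-0.31). Of the 20 lists inside the bounds, 5 passed them under an alternative: cell cycle (high in pool 3 under 4 and low in pool 1 under 2), the ciliary body, cornea and sclera list (high in pool 3 under 4, low in pool 2 under 1), heat shock (low in pool 2 under quantile and cyclic loess), glycolysis (low in pool 3 under 2, high in pool 2 under 1) and immediate early (low in pool 1 and high in pool 2 without pool 3). The 6 values past the bounds numbered 4 to 10 with a pool left out. With 2 pools left, a list's values are 1 difference with opposite signs, so each such list counts as 2 values. Where no construction is named, the cause was not tested. Signals near the floor limit the pigment epithelium list: 3 of its 6 genes passed it on every array, too few to rank.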

Other observations

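The tests of X-linked genes and of paired probe sets below were set out beforehand; the rank of the X-linked genes among random genes was added, and all genes named in the next paragraph outside the fixed rule were chosen, after the results were seen.

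The array of pool 1 also had the highest 3' to 5' ratios of Gapdh and beta-actin (0.916 and 1.77) and the most probe sets over 2-fold from the others (177 and 178, against 38 between pools 2 and 3). Of 12 heat shock genes, 11 were higher in pool 1, with a median deviation of 0.17 (percentile 94.6), and 9 were lower in pool 2, with -0.18 (percentile 1.29). The pool 2 value was just inside the bounds and passed them with quantile (percentile 0.29) and cyclic loess (0.43) normalisation. The inducible chaperones Hspa1a (1221, 601.0 and 629.0 in pools 1, 2 and 3) and Hspa1b (908.6, 460.4 and 544.7) spanned 2.00-fold and 1.94-fold, while Dnajb1 stayed within 1.08-fold. Among Müller glia genes, the lipid carrier Apoe was highest in pool 1 (12382, 7103 and 5872) and clusterin, Clu, was highest in pool 3 (4882, 5487 and 8463). The 4 cell cycle genes above the floor were all lower in pool 1, with Pcna, the replication clamp, at 565.7, 875.4 and 1176 and a list median of -0.46 (percentile 2.50). The collagen gene Col1a1, of sclera and other connective tissue, was at 90.4, 302.1 and 556.0, while its partner chain Col1a2, which forms the same collagen, was lowest in pool 3 (1326, 1221 and 939.4). Their list had a median of 0.33 in pool 3 (percentile 97.3).

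One hypothesis is that the pools held differing shares of female mice, which may explain the Xist values. It predicted that X-linked genes escaping inactivation would be higher in pool 3 than in pool 1 by over 0.1 on the log2 scale and that Eif2s3y would be lower there. The median difference of 3 such genes was 0.56, from 0.31 for the least to 0.73 for the most, at percentile 97.3 among 10000 random sets of 3 genes. Eif2s3x was at 3684, 5181 and 5362 in pools 1, 2 and 3, Kdm6a at 1014, 1253 and 1660, and Ddx3x at 1426, 1671 and 1749. The probe set of Ddx3x may match several genes. Both predictions were met. Eif2s3y, however, was in the same list as Xist, whose values raised the hypothesis, so only the 3 escaping genes were a separate test. That set is small, array 1 differed from the others for many genes, and the Y-linked signals lie near or under the floor.

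Another hypothesis is that the differences between pools are in the RNA and not in single probe sets. Pairs of probe sets above the floor were taken for 539 genes, which are not independent replicates. Only probe sets with the suffix g were left out, so a pair could hold other suffixes, some of which mark possible matches to several genes. The deviations of both probe sets correlated with Pearson r of 0.346, 0.237 and 0.270 in pools 1, 2 and 3. Spearman rho was 0.325, 0.144 and 0.264. For the 3 Pearson values the two-sided permutation p was 1e-05, the smallest that 100000 permutations can give, and 1e-05 after Benjamini-Hochberg adjustment; for rho in pool 2 it was 0.00058 before and after adjustment, and for the other rho values 1e-05 and 1.5e-05. The prediction asked for r above 0.3 in each pool, which only pool 1 reached, and the lowest, 0.237, lay above the 0.1 that would have argued against it. RNA differences may therefore account for part of the spread, and differences of tissue and of RNA handling both count as such. Pairs with suffixes, such as that of Cryge (-1.77 and -1.34 in pool 2), may match the same sequences. The correlation therefore does not fully separate RNA differences from probe set effects.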
